A study of Homo sapiens with 8 samples.

How the data were processed

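Total RNA from 8 samples of BT-20 cells (siEGFP or siSALL3, 48 h or 96 h after transfection with 50 nM siRNA, 2 samples per group) was amplified, labelled with Cy3 and hybridised to 1-colour Agilent human expression arrays, per the labels' protocols. The deposited files hold the scanner output of each array, with fluorescence intensity on a linear scale per spot, extracted by Agilent Feature Extraction version 10.7.1.1 per the file headers and 9.5 per the submitters' processing notes. The processed signal that the authors deposited is an intensity after Feature Extraction's background subtraction, not normalized between arrays. The authors' value table of the series holds linear intensity too: at least 99.3% of its values per array lay within 1% of the mean processed signal of the probe, so its scale is linear, it is not centred, and it is no independent set. Its medians per array ranged from 11.9 to 19.5. The genome build in the files differs from that of the gene table used here, so no coordinates are given.

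Each array has 62976 spots, of which 58717 were not controls and gave 50599 probes. Spots with outlier flags were left out, spots of one probe were averaged, and log2 of the processed signal minus the 75th percentile of the array was used. The files pair no gene names with probes. Probes were named through their accession in a RefSeq gene table of assembly GRCh38.p14: 28174 probes had 1 symbol, 0 had several and 22425 had none and are unnamed here. A probe was kept if it was well above background on both arrays of at least 1 group and had a value on all 8 arrays (25426 probes), and the probe with the highest mean stood for each gene, which gave 20181 genes, 14106 with a symbol. Of 4024 genes with several kept probes, probes passed the test in opposite directions for 45 at 48 h and 310 at 96 h.

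A model with a mean for each of the 4 groups was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 4 residual and 1.85 prior degrees of freedom, and adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The median replicate SD was 0.0746 and the median SE of a time-matched comparison 0.101 on the log2 scale. The contrasts were siSALL3 against siEGFP at 48 h, at 96 h and averaged over times, siSALL3 at 96 h against siEGFP at 48 h as in the study, siEGFP at 96 h against 48 h, and the difference between the time-matched effects. The deposited signal sets a floor: where a probe was not well above background on any array of a group, the fold is a bound. It is the bright group's mean over the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. List medians were also taken with such groups set to that floor. Changes without the word fold are on the log2 scale.

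Before the data were examined, 35 gene lists were fixed, and 771 of their 783 symbols were on the array and 669 were tested. The 32 lists with at least 5 tested genes were tested with camera, with a preset inter-gene correlation of 0.01 and again with the estimated correlation, adjusted over the lists of a comparison. The genes named were fixed by a rule before the data were examined: the 10 largest rises and 10 largest falls in each time-matched comparison among genes with a symbol, an adjusted p under 0.05 and both arrays of one group beyond both of the other, 8 and 8 with time, 10 and 10 by mean change over both times, 5 and 5 for the difference between times, and up to 4 per list by the averaged change. Where fewer passed, those are named, and 1 Y-linked gene and some other genes that met the rule are left out. Lists and genes outside these rules are said to be so.

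Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the authors' value table, other filters on dim probes, flagged spots kept, the mean of a gene's probes, an intensity trend in the prior, fits of the compared groups alone, a replicate block, other thresholds, and leaving out each array in turn, where a lone array is assumed to vary like the other groups. Overlaps were set against 100 simulations of unchanged groups with the shared arrays. The procedure was tested on simulated data for the 48 h comparison with 20181 genes: 78 of 100 genes changed by 1 on the log2 scale and 96 of 100 changed by 2 were recovered, with 8 false calls. No batch could be tested, since all arrays lay on 1 slide and were scanned in 1 run. Figures were drawn with matplotlib 3.10.9.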

Results

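The series asks which genes respond in a triple-negative breast cancer cell line when SALL3, a zinc finger transcription factor of the spalt family, is targeted by RNA interference. BT-20 is an established line of triple-negative breast cancer, a tumour type that lacks the oestrogen and progesterone receptors and amplified HER2. The cells received 50 nM of siRNA against SALL3 (siSALL3) or of a control siRNA against EGFP (siEGFP), a jellyfish gene that human cells lack. RNA was taken 48 h and 96 h later, with 2 samples in each of the 4 groups, and each sample was hybridised to its own 1-colour Agilent expression array. Between 22257 (siEGFP 96 h, replicate 2) and 25851 (siEGFP 48 h, replicate 1) of the 50599 probes were well above background, and 20181 genes were tested. The number of arrays limits the precision. Nothing in the labels says whether the 2 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The 8 arrays lay on 1 slide, with the times in different slide rows and the siRNAs in different columns, so position on the slide and group cannot be told apart.

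The targeted gene was measured by 1 probe, which was well above background on all 8 arrays. On the log2 scale relative to each array's 75th percentile, SALL3 read 0.72 ± 0.026 (SD, n = 2) in siEGFP cells at 48 h and 0.58 ± 0.11 (SD, n = 2) in siSALL3 cells. The difference of -0.14 (SE 0.073, 95% interval -0.32 to 0.044) left SALL3 at 91.0% of the control and did not pass limma's test (adjusted p = 0.215). At 96 h SALL3 read 0.84 ± 0.021 in siEGFP cells and 0.40 ± 0.045 in siSALL3 cells (SD, n = 2 each). It fell by 0.43 (SE 0.073, 95% interval -0.61 to -0.25), to 74.0% of the control, with an adjusted p of 0.00328. By size of the fall, SALL3 ranked 6971 of 20181 genes at 48 h and 5123 at 96 h, and its interval excluded a 2-fold loss at both times. Of the other family members, SALL4 differed by -0.23 (SE 0.35, adjusted p = 0.669) at 48 h and fell by 1.06 at 96 h (adjusted p = 0.0425). The siEGFP 96 h arrays differed, and the SALL4 change was -0.69 under normexp, -0.48 without replicate 1 of that group and -1.64 without replicate 2. The call ended without either siSALL3 96 h array, replicate 1 (adjusted p = 0.136) or 2 (0.128). It also ended without siEGFP 48 h replicates 1 and 2 (0.0712 and 0.0755) and siSALL3 48 h replicates 1 and 2 (0.0722 and 0.0729). SALL1 and SALL2 did not meet the detection rule. SALL3 and SALL4 were the tested members of the SALL family list, of which 0 changed at 48 h, 2 fell at 96 h and 0 changed with time in siEGFP cells, adjusted over all genes or adjusted over the list alone.

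**Figure D1:**
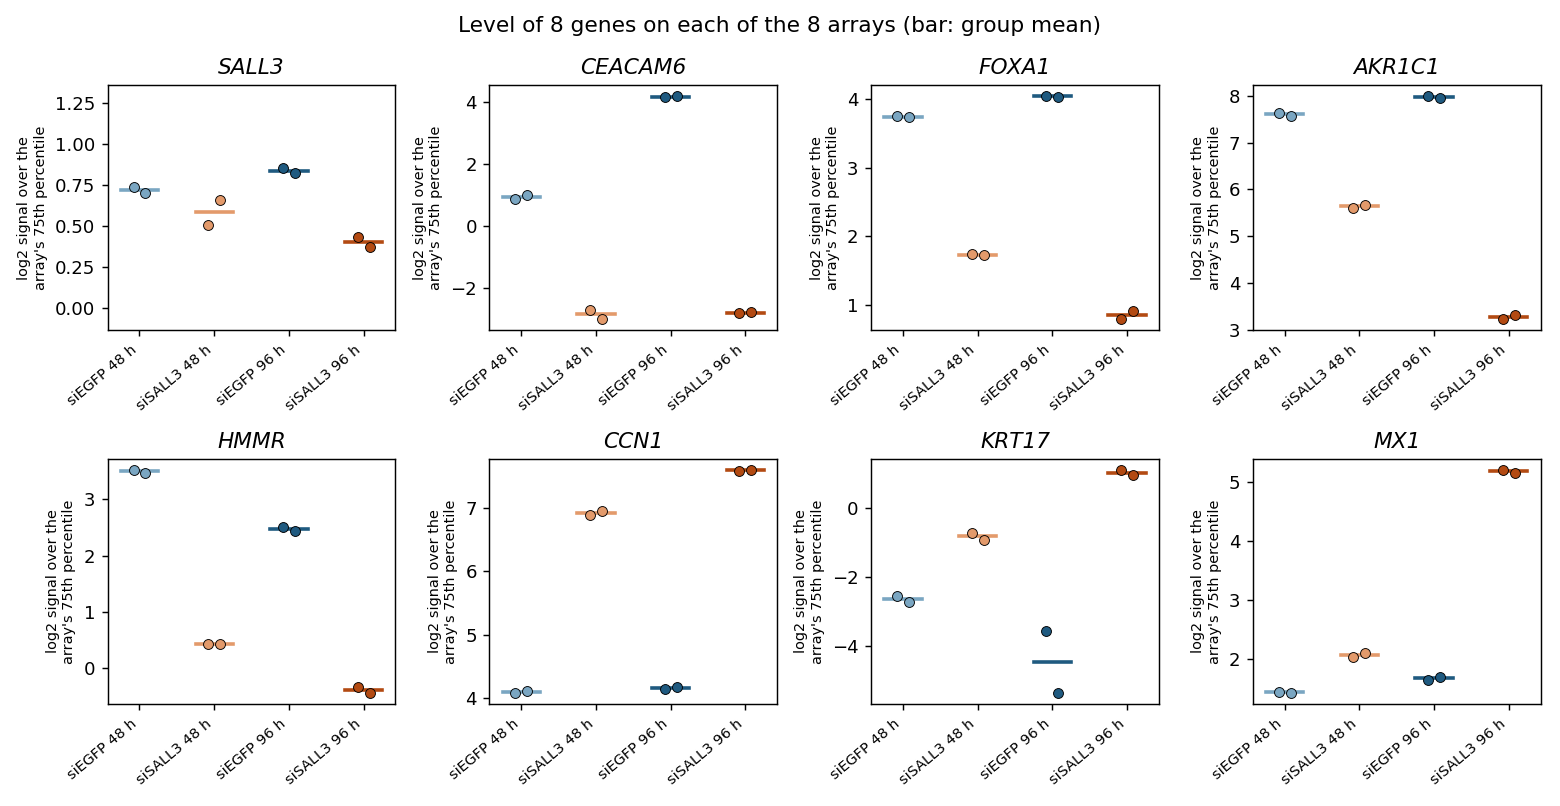
Log2 signal of 8 genes over the 75th percentile of each array (y axis, with its own range per gene) in the 4 groups of 2 arrays (x axis); points are arrays and bars are group means. SALL3 fell by 0.43 at 96 h, while CEACAM6 was 6.96 lower and MX1 3.52 higher in siSALL3 than in siEGFP cells at that time. CEACAM6 rose with time in siEGFP cells.

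The first comparison asked which genes differed 48 h after transfection. In siSALL3 cells CEACAM6, a cell surface adhesion molecule, fell by 3.77 (SE 0.11, n = 2 arrays per group, limma adjusted p = 9.52e-05). Its relative CEACAM7 fell by 3.24, and DMBT1, a secreted mucosal glycoprotein, fell by 3.03. The stem cell factor SOX2 was at least 2.26-fold lower. Among genes well above background on all 48 h arrays, SEMA7A, a membrane-anchored semaphorin (log2 change 3.47, SE 0.15), OXTR, the oxytocin receptor (3.38, SE 0.084), and FSTL1, a secreted glycoprotein (2.89, SE 0.078), rose. Under normexp background correction, which shrinks the changes of dim probes, CEACAM6 was at -2.46, CEACAM7 at -1.53 and SEMA7A at 2.02. Genes that were not well above background on either siEGFP array have only a bound. VSTM1 was at least 11.9-fold higher, WLS, which carries Wnt proteins to the cell surface, at least 7.73-fold higher, and the cytokine gene IL6 at least 6.28-fold higher. DACT1, CLEC18C, RUBCNL and HCN4 were higher by at least 2.92-fold, 2.85-fold, 2.75-fold and 1.89-fold. HMMR, a spindle and hyaluronan binding protein, fell by 3.06 (SE 0.066), with an adjusted p of 4.97e-05. IMPG2, LRRTM1, YY1P2 and GALNT13 were lower by at least 7.89-fold, 5.26-fold, 5.25-fold and 3.96-fold, each against siSALL3 arrays on which it was not well above background. IMPG2, LRRTM1, YY1P2, GALNT13 and CLEC18C were not well above background on any 96 h array. Some bounds rest on a single array: without siSALL3 48 h replicate 2 that of CLEC18C was 1.55-fold, without siEGFP 48 h replicate 2 that of LRRTM1 2.98-fold, and without siEGFP 48 h replicate 1 that of GALNT13 1.52-fold. The VSTM1 call ended without siEGFP 48 h replicate 1 or 2 and without siSALL3 48 h replicate 1 or 2. Those arrays agreed within groups (-5.441 and -5.691 in siEGFP, -0.763 and -0.702 in siSALL3 cells). The siEGFP 96 h arrays read -2.552 and -5.614 for VSTM1, and their spread enters its test, since the 4 groups share 1 estimate of spread. The GALNT13 call ended without siSALL3 48 h replicate 1 or 2.

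In all, 6615 of the 20181 genes passed limma's test at 48 h, 3482 higher and 3133 lower in siSALL3 cells. Of these, 905 also changed over 2-fold, 450 up and 455 down. The count was 3641 without siEGFP 48 h replicate 1, 3739 without siEGFP 48 h replicate 2 and 4277 without siSALL3 48 h replicate 1.

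Among 32 gene lists with enough members for camera, 5 changed at 48 h, and none of the 5 calls held with an estimated correlation. Without siEGFP 48 h replicate 1, 3 lists changed. Genes of G1/S and DNA replication rose: 22 of 41 rose, 2 fell and 17 were not called (camera adjusted p = 7.50e-06, and adjusted p = 0.116 with an estimated correlation). Examples were UNG, a uracil glycosylase (0.86), cyclin E1, CCNE1 (0.63), and the origin recognition gene ORC6 (0.53), whereas RRM2, a subunit of ribonucleotide reductase, fell by 0.91. Targets of YAP and TEAD, the Hippo pathway's transcription factors, also rose, with 10 of 13 higher and 1 lower (adjusted p = 2.48e-05, and adjusted p = 0.284 with an estimated correlation). They included CCN1, a matricellular protein (2.83, SE 0.059), the tissue factor gene F3 (1.75) and the Hippo kinase gene LATS2 (1.61). Targets of NRF2, the regulator of the oxidative stress response, fell, with 14 of 22 lower and 2 higher (adjusted p = 2.48e-05, and adjusted p = 0.284 with an estimated correlation). The aldo-keto reductases AKR1C1 and AKR1C3 fell by 1.96 and 1.16, and AKR1B10 fell by 0.73. Of the G1/S and DNA replication genes, 25 rose and 2 fell when adjusted over the list alone, and the counts for the YAP and TEAD and the NRF2 lists were those given.

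Luminal mammary markers were lower as a list at 48 h, with 5 of 12 lower, 1 higher and 6 not called (camera adjusted p = 0.0270, and adjusted p = 0.315 with an estimated correlation). The pioneer factor gene FOXA1 fell by 2.01 (SE 0.064), the epithelial transcription factor gene SPDEF fell by 2.13 (SE 0.40) and the mucin gene MUC1 fell by 1.23. The SPDEF call ended without siEGFP 48 h replicate 1 or 2 and without siSALL3 48 h replicate 1 or 2. Those arrays agreed within groups (1.737 and 1.755 in siEGFP, -0.319 and -0.45 in siSALL3 cells). The siSALL3 96 h arrays read -1.163 and 0.175, and their spread enters the SE, since the 4 groups share 1 estimate of spread. Squamous differentiation genes were lower too, with 7 of 18 lower and 1 higher (adjusted p = 0.0270, and adjusted p = 0.414 with an estimated correlation). The calprotectin gene S100A8 fell by 1.38, S100A7 fell by 1.03 and the kallikrein gene KLK7 fell by 1.33, while the transglutaminase gene TGM1 rose by 0.70 (-0.36, -0.70 and 0.45 under normexp for the last 3). Adjusted over the list alone, 5 luminal genes were lower and 1 higher, and 7 squamous genes were lower and 2 higher. The luminal call ended without siEGFP 48 h replicate 1 (adjusted p = 0.0638), siEGFP 96 h replicate 1 (0.0570) or siSALL3 48 h replicate 2 (0.0600). The squamous call ended without siEGFP 48 h replicate 1 (0.0582) or siEGFP 96 h replicate 2 (just above the threshold, with a median of -0.26).

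The other 27 lists did not pass camera at 48 h, although single members moved. Of 18 NF-kB and inflammatory cytokine genes 8 rose and 2 fell (adjusted p = 0.0535), with TNF at 2.51 (1.41 under normexp), LIF at 1.60 and the chemokine gene CCL2 at least 1.86-fold higher. Without siEGFP 48 h replicate 2 this list passed (adjusted p = 0.0158). Of 23 genes of ERK feedback and the immediate early response 10 rose and 7 fell, among them the phosphatase genes DUSP1, which rose by 1.75, and DUSP6, which fell by 1.36 (-0.79 under normexp). Of 27 apoptosis regulators 5 rose and 5 fell, with BAK1 at 2.05 and BIK at 1.04, and of 23 p53 targets 9 rose and 2 fell, with GADD45A at 1.79. Of 33 interferon-stimulated genes 8 rose and 2 fell (adjusted p = 0.499). Of 40 genes of G2/M and mitosis 4 rose and 5 fell (adjusted p = 0.671), and apart from HMMR the lowest was KIF11, a spindle motor gene, which fell by 0.49. Of 28 epithelial adhesion genes 5 rose and 7 fell, and of 15 basal mammary markers 6 rose and 2 fell. Counts that rose and fell were 7 and 2 of 16 mesenchymal genes, 9 and 1 of 27 DNA repair genes and 0 and 9 of 25 lysosome and autophagy genes. The repair list passed without siEGFP 48 h replicate 2 (adjusted p = 0.0296) and the lysosome list without siSALL3 48 h replicate 1 (0.0341). Counts were 11 and 3 of 28 hypoxia and glycolysis genes, 4 and 1 of 24 cholesterol synthesis genes, 3 and 7 of 18 fatty acid synthesis genes, and 4 and 2 of 20 matrix remodelling genes. Further counts were 4 and 2 of 12 DNA methylation genes (with TDG at 1.19), 5 and 3 of 12 CDK inhibitors and G1 cyclins, 1 and 4 of 11 EGFR family genes, 3 and 4 of 14 TGF-beta targets, 5 and 3 of 10 Wnt targets and 4 and 5 of 14 Notch targets. For stress and housekeeping lists they were 6 and 5 of 34 genes of amino acid stress and the unfolded protein response, 4 and 2 of 16 heat shock genes, 6 and 3 of 13 RNA interference genes, 0 and 0 of 39 cytosolic ribosomal protein genes, and 2 and 2 of 29 oxidative phosphorylation genes. Among markers of other cell types, 0 of 3 fibroblast, 1 of 9 immune and 2 of 4 endothelial genes changed, the endothelial pair being ESAM (0.69, or 0.43 under normexp) and VWF, which fell by 1.02 (-0.54 under normexp, and -0.51 with the mean of its probes, which ended its call with an adjusted p of 0.0695). Counts that rose and fell adjusted over the list alone differed for G2/M and mitosis (2 and 4), CDK inhibitors (6 and 4), p53 targets (9 and 4), apoptosis (6 and 5), ERK feedback (10 and 8) and epithelial adhesion (5 and 8). They also differed for basal markers (7 and 2), TGF-beta (6 and 4), hypoxia (12 and 4), lysosome (1 and 9), RNA interference (7 and 4) and oxidative phosphorylation (0 and 0). Median, mean and test differed in sign for G2/M and mitosis (median 0.014, mean -0.081, test down), fatty acid synthesis (0.019, -0.10, down) and Notch targets (0.0071, 0.050, down).

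The next comparison asked which genes differed at 96 h from siEGFP cells of the same age. CEACAM6 was 6.96 lower than in siEGFP cells (SE 0.11, adjusted p = 3.05e-06). CEACAM7 had a log2 change of -6.51, DMBT1 -6.11, and PIP, the prolactin-inducible protein gene, -5.66. In siSALL3 cells CEACAM6 read -2.711 and -3.015 at 48 h and -2.819 and -2.8 at 96 h. In siEGFP cells it rose from 0.842 and 0.979 to 4.132 and 4.175, so its larger difference at 96 h was measured against a higher control. CEACAM7, DMBT1 and PIP also rose with time in siEGFP cells. CEACAM3 and SOX2 were at least 8.43-fold and 8.15-fold lower, C9orf152 at least 7.74-fold lower (3.19-fold without siEGFP 96 h replicate 1), and CYP4Z1, a cytochrome P450 gene, fell by 5.03. In the other direction, ANKRD2, a stretch-responsive ankyrin repeat gene, rose by 5.34 (SE 0.057, adjusted p = 2.60e-06), and ZBED2, SEMA7A and WLS were at least 47.4-fold, 43.2-fold and 40.9-fold higher. KRT17, a basal keratin gene, was at least 22.2-fold higher, and PSG8, a pregnancy-specific glycoprotein gene with near-identical relatives, at least 10.3-fold higher. With the mean of its probes PSG8 had a fitted log2 change of 3.03, less than that bound. VSTM1, and TNNC1, a troponin gene, had log2 changes of 5.64 and 5.17, each with 1 of the 2 siEGFP arrays well above background. Under normexp VSTM1 was at 3.26, TNNC1 at 3.07 and CYP4Z1 at -3.34, and the fitted log2 changes of genes given as bounds shrank too, to 3.59 for ZBED2, 3.55 for SEMA7A, 3.64 for WLS, 2.83 for KRT17 and 1.87 for PSG8. CMYA5 and IFI44 were at least 8.94-fold and 8.87-fold higher and TMEM71 at least 24.7-fold lower. Each of these 3 probes was well above background on the 2 arrays of a single group only. Across the array set 938 probes were bright on a single array and not well above background on the other 7, and 784 of these were on 96 h arrays.

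At 96 h 12102 of 20181 genes passed limma's test, 6238 higher and 5864 lower in siSALL3 cells. Of these, 3647 changed over 2-fold, 1926 up and 1721 down. The calls include IMPG2 (-0.60), which was not well above background in either group and was at -0.032 under quantile normalization. With no filter on dim probes, 5830 were higher and 12433 lower.

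Camera called 13 of the 32 lists at 96 h, and 2 of the calls held with an estimated correlation. The first of these was G1/S and DNA replication, with 39 of 41 genes higher and 1 lower (adjusted p = 9.72e-10, and adjusted p = 0.0344 with an estimated correlation). The other was interferon-stimulated genes, with 27 of 33 higher and 1 lower (adjusted p = 1.47e-08, and adjusted p = 0.0344 with an estimated correlation). ORC6 rose by 1.81, UNG by 1.22 and CCNE1 by 1.18, and RRM2 again fell, by a log2 change of -0.95. In siEGFP cells these replication genes fell between 48 h and 96 h, so the 96 h difference was measured against a lower control. Among interferon-stimulated genes, the antiviral GTPase gene MX1 rose by 3.52 (SE 0.063, adjusted p = 3.12e-06) and OASL was at least 10.6-fold higher. IFI44L, well above background on the siSALL3 96 h arrays only, was at least 3.21-fold higher. DNA repair genes were higher, with 20 of 27 up and 0 down (adjusted p = 0.000107, and adjusted p = 0.197 with an estimated correlation), among them RAD54L and RAD18, both at 1.24. Of 24 cholesterol synthesis genes 20 rose and 3 fell (adjusted p = 8.24e-05, and adjusted p = 0.0863 with an estimated correlation), with INSIG1 at 1.30 and ACAT2 at 1.29. When adjusted over the list alone, the counts of these 4 lists were those given, except that 1 DNA repair gene fell.

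Luminal mammary markers fell at 96 h, with 8 of 12 lower and 0 higher (camera adjusted p = 0.000372, and adjusted p = 0.0942 with an estimated correlation). FOXA1 had a log2 change of -3.19 (SE 0.064), MUC1 -2.27 and SPDEF -2.16, and AGR2 was at least 3.53-fold lower (fitted log2 change -0.98 under normexp). For SPDEF the siSALL3 96 h arrays differed, at -1.163 and 0.175. Basal mammary markers rose, with 9 of 15 higher and 3 lower (adjusted p = 0.0488, and adjusted p = 0.197 with an estimated correlation). Caveolin 1, CAV1, rose by 2.96, and the basal keratin genes KRT14 and KRT16 by 2.85 and 2.50, KRT14 by 1.39 with the mean of its probes and 1.73 under normexp. This call ended without siEGFP 48 h replicate 1 (adjusted p = 0.0891), siEGFP 96 h replicate 1 (0.151) or siSALL3 96 h replicate 2 (0.109). Mesenchymal genes rose in 9 of 16 cases and fell in 2 (adjusted p = 0.0265, and adjusted p = 0.197 with an estimated correlation). The smooth muscle gene TAGLN rose by 3.20, and the transcription factor genes SNAI2 and ZEB1 were at least 4.39-fold and 2.98-fold higher. With no filter on dim probes the list's median was -0.013 in place of 0.66 and the call was lost. It was also lost without siEGFP 48 h replicate 1 (0.0625) or siEGFP 96 h replicate 1 (0.0917). Matrix remodelling genes rose in 13 of 20 cases and fell in 2 (adjusted p = 0.00781, and adjusted p = 0.181 with an estimated correlation). The basement membrane collagen gene COL4A2 rose by 3.03, and PLAU, urokinase, was at least 2.06-fold higher. Under normexp PLAU had a fitted log2 change of 0.46, less than that bound. Squamous differentiation genes fell, with 13 of 18 lower and 3 higher (adjusted p = 0.00506, and adjusted p = 0.316 with an estimated correlation), S100A8 and S100A7 by log2 changes of -3.24 and -3.01, S100A7 by -1.76 under normexp. Adjusted over the list alone, counts that rose and fell were 0 and 8 for luminal, 9 and 3 for basal, 10 and 2 for mesenchymal, 14 and 2 for matrix and 3 and 13 for squamous genes.

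NRF2 targets were lower at 96 h in 20 of 22 cases and higher in 1 (camera adjusted p = 1.53e-07, and adjusted p = 0.0942 with an estimated correlation). AKR1C1 fell by 4.70 (SE 0.065), AKR1C3 by a log2 change of -3.27 and AKR1B10 by -2.74. Aldo-keto reductases within the AKR1C family, and within the AKR1B family, are close relatives whose probes may not tell them apart. YAP and TEAD targets stayed higher, with 10 of 13 up and 1 down (adjusted p = 0.00176, and adjusted p = 0.197 with an estimated correlation), CCN1 at 3.45 and LATS2 at 2.96, with ANKRD1 at least 2.35-fold higher. Hypoxia and glycolysis genes rose in 17 of 28 cases and fell in 4 (adjusted p = 0.0120, and adjusted p = 0.170 with an estimated correlation), with ENO2 at 2.27 (1.49 under normexp) and ADM, adrenomedullin, at 2.06. Cytosolic ribosomal protein genes were lower in 23 of 39 cases and higher in 0, with a small median of -0.25 (adjusted p = 0.000381, and adjusted p = 0.643 with an estimated correlation), and RPL3 fell by 0.65. Under quantile normalization RPL3 was at -0.42, the ribosomal median was 0.086 and the call was lost, as it was under normexp (adjusted p = 0.0642). There were 22 lower ribosomal genes adjusted over the list alone, and the counts of the NRF2, YAP and TEAD, and hypoxia lists were those given.

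**Figure D2:**
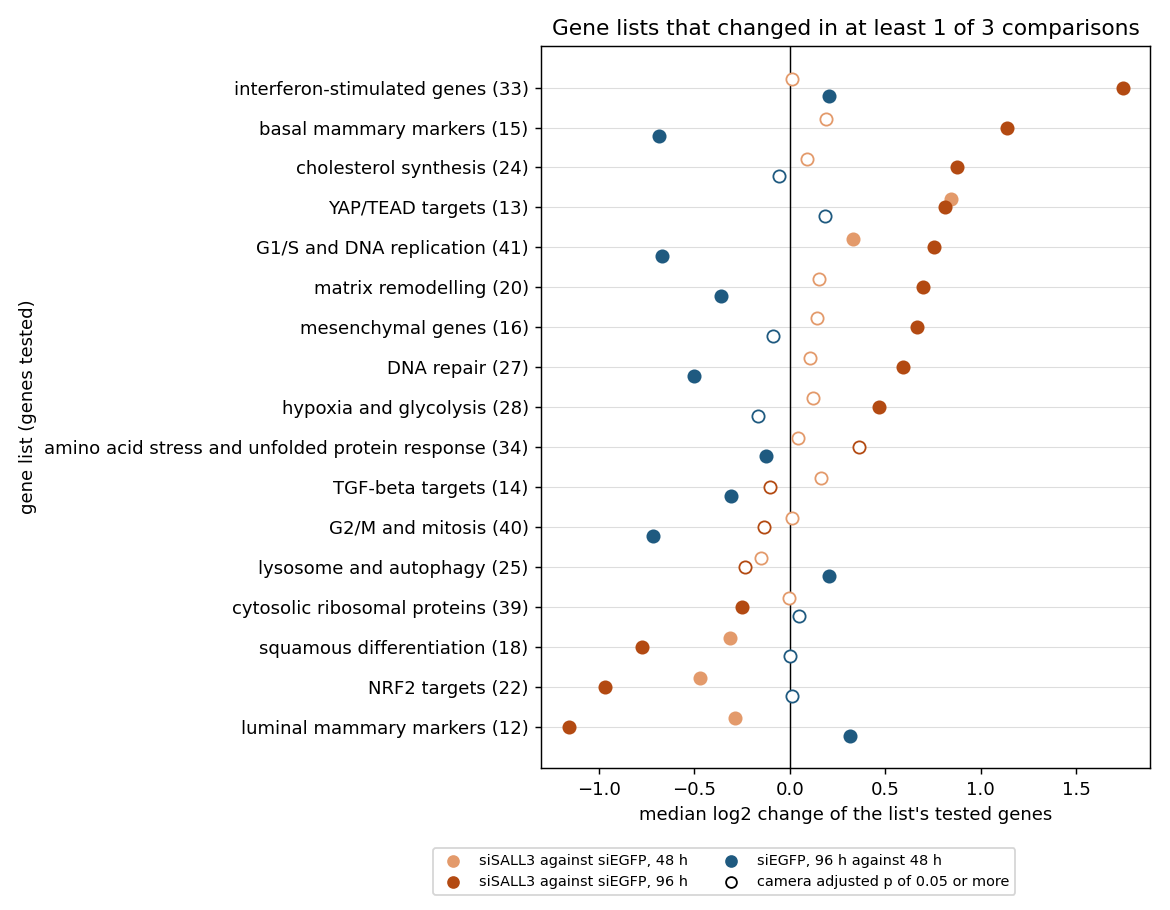
Median log2 change of the tested genes (x axis) of the 17 gene lists (y axis) that camera called in at least 1 of 3 comparisons: siSALL3 against siEGFP at 48 h and at 96 h, and siEGFP at 96 h against 48 h. Filled points passed camera's adjusted p threshold with the preset correlation and open points did not; interferon-stimulated genes had the highest median at 96 h (1.74, or 1.66 with dim groups set to the floor of the bounds) and luminal mammary markers the lowest (-1.15), and the ribosomal and mesenchymal medians at 96 h changed sign under another processing.

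The remaining 19 lists did not pass camera at 96 h. Genes of G2/M and mitosis split, with 14 of 40 higher and 17 lower (adjusted p = 0.545): the cytokinesis gene ANLN rose by 1.15, the spindle genes CENPE and KIF11 fell by 1.02 and 0.94, and HMMR fell by 2.87. Genes of amino acid stress and the unfolded protein response rose in 18 of 34 cases and fell in 8 (adjusted p = 0.0672), with CHAC1 at 2.08, SESN2 at 2.03, ATF3 at 1.76 (1.11 with the mean of its probes) and XBP1 at -1.82. Of 23 p53 targets 7 rose and 6 fell, GADD45A by 3.63 and DDB2 by 2.12 against -2.73 for TP53INP1, and of 27 apoptosis regulators 10 rose and 8 fell, BAK1 by 2.67 against -3.30 for BMF. Of 11 EGFR family genes 2 rose and 3 fell. HBEGF, a ligand of the EGF receptor, was at least 3.50-fold higher, and LRIG1 changed by -1.65. Of 23 ERK feedback and immediate early genes 10 rose and 9 fell, with DUSP1 at 2.66, FOSL1 at 2.51 and DUSP6 at -2.33. Of 28 epithelial adhesion genes 7 rose and 11 fell, with CDH3, P-cadherin, at 1.60 and ELF3 at -1.80. Of 25 lysosome and autophagy genes 5 rose and 13 fell (adjusted p = 0.0646), with TFEB at -2.26 (-1.08 with the mean of its probes). Without siSALL3 96 h replicate 2 the lysosome list passed (adjusted p = 0.0474).

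Counts of members that rose and fell at 96 h were 4 and 4 of 18 NF-kB genes (LIF at 2.98), 7 and 2 of 12 DNA methylation genes (DNMT1 at 0.80, TDG at 1.11), and 5 and 4 of 12 CDK inhibitors and G1 cyclins (CDKN2C at -1.42). For signalling targets they were 4 and 6 of 14 TGF-beta targets (THBS1 at 2.02, ID1 at -2.45), 4 and 4 of 10 Wnt targets (DKK1 at 2.54, or 1.63 under normexp, WNT5A at -1.58), and 5 and 5 of 14 Notch targets (DLL3 at 2.61). They were 7 and 7 of 18 fatty acid synthesis genes (FADS2 at 1.16), 8 and 2 of 16 heat shock genes (CRYAB at 2.27, and HSPA4L at 3.40 with 1 of the 2 siEGFP arrays well above background, or 1.81 under normexp), 7 and 5 of 13 RNA interference genes (AGO3 at 1.41, and AGO1 at -1.38, or -0.20 with the mean of its probes, which ended its call with an adjusted p of 0.0554) and 9 and 5 of 29 oxidative phosphorylation genes (UQCRC2 at -0.70). Among markers of other cell types, 1 of 3 fibroblast genes rose (COL1A1 at 0.68, or 0.24 under normexp), 3 of 9 immune genes rose and 2 fell (CSF1R at 1.63, or 0.92 under normexp, CD4 at -0.70), and 1 of 4 endothelial genes rose and 2 fell (ESAM at 1.69, or 0.78 under normexp, and VWF at -1.66, or -0.94 under normexp and -0.56 with the mean of its probes). Adjusted over the list alone, counts that rose and fell differed among these 19 lists for apoptosis (11 and 9), the EGFR family (2 and 2), fatty acid synthesis (7 and 8), the unfolded protein response (19 and 8), lysosome (5 and 14), oxidative phosphorylation (7 and 5) and immune markers (3 and 1). Median, mean and test differed in sign for TGF-beta targets (median -0.10, mean 0.22, test down), the EGFR family (-0.14, 0.11, down), CDK inhibitors (0.0042, -0.052, down) and Notch targets (0.0018, 0.093, down).

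The study's own rule asked which genes changed over 2-fold in the same direction in siSALL3 cells at 48 h and at 96 h, both set against siEGFP cells at 48 h. By that rule 915 genes were common, 470 higher and 445 lower, and 792 of them also had an adjusted p under 0.05 in both comparisons by limma. Among them were WLS, SEMA7A, OXTR, IL6, ADAMTS9 and S100A3 on the higher side, and CEACAM6, CEACAM7, DMBT1 and AKR1C8 on the lower side. The rule uses fitted means. ADAMTS9 and S100A3 were not well above background on either siEGFP 48 h array, and their bounds at 48 h were 1.41-fold and 3.11-fold. The bound of ADAMTS9 is thus under 2-fold. Under normexp their log2 changes at 48 h were 0.55 and 0.74. The rule compares 96 h with 48 h across siRNAs, so it mixes the siRNA with time in culture. Of the 915 common genes, 805 (88.0%) also changed over 2-fold the same way against siEGFP cells at 96 h, and 96 changed over 2-fold the same way with time in siEGFP cells alone and 91 the opposite way. Simulated groups with no effect that shared the siEGFP 48 h arrays gave 41.8 common genes. Part of the excess may come from those shared controls, which are too few to split. Under normexp background correction 258 genes were common and with probes well above background on all 8 arrays 459, against 1621 with no filter (642 higher, 979 lower) and 1498 without siEGFP 48 h replicate 2. Against siEGFP cells at 48 h, 10948 genes passed the test in siSALL3 cells at 96 h, 5275 higher and 5673 lower.

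Between the time-matched comparisons, 5803 genes passed the test at both times in the same direction, 3144 higher and 2659 lower, against 1076 and 910 for independent lists, and 118 passed in opposite directions. Of the shared genes, 85.1% had the larger change at 96 h. Across genes, which are not independent replicates, the changes had a Pearson r of 0.697 and a covariance of 0.337 (simulated with no effect, -0.00341 and -0.000150), and these comparisons share no array. The genes with the largest mean fitted change over both times included ZBED2 (2.59 at 48 h and at least 47.4-fold at 96 h), ADAMTS9 and RUBCNL on the higher side. ADAMTS9 was at least 1.41-fold higher at 48 h and 5.04-fold at 96 h, and RUBCNL at least 2.75-fold and 4.83-fold. On the lower side were CXCL17 (-2.68 and -4.90) and SIDT1 (-2.91 and -4.53), each with 1 of the 2 siSALL3 96 h arrays well above background. Under normexp these were -1.33 and -3.11, and -1.50 and -2.61, and ZBED2 was at 1.51 at 48 h. Others were AKR1C8 (-2.12 and -4.99), CLCA2 (at least 2.71-fold and 7.41-fold lower) and MSMB (at least 1.78-fold and 4.85-fold lower). The count of shared genes was 3305 and 3286 without siEGFP 48 h replicates 1 and 2, and 3694 and 3861 without siSALL3 48 h replicates 1 and 2.

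**Figure D3:**
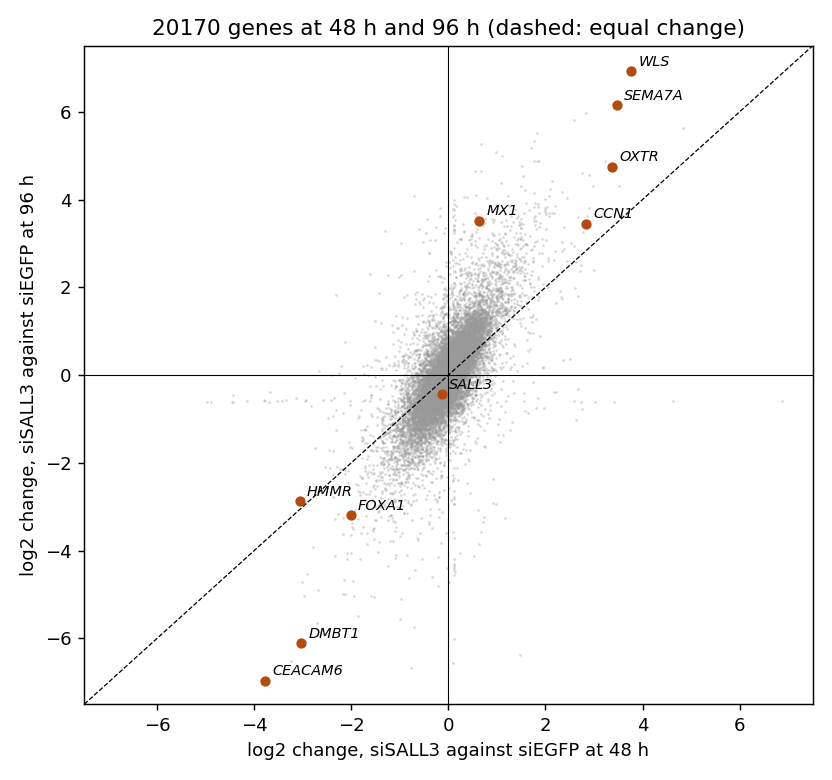
Log2 change in siSALL3 against siEGFP cells at 48 h (x axis) and at 96 h (y axis) for 20170 genes; each point is a gene and the dashed line marks equal change. CEACAM6, DMBT1, WLS and SEMA7A lie farther from 0 at 96 h, whereas HMMR (-3.06 and -2.87) lies near the line. CEACAM6 and DMBT1 also rose with time in siEGFP cells.

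The change with time in siEGFP cells gives the background against which the 96 h comparison was measured. Genes of cell division fell between 48 h and 96 h. All 40 tested genes of G2/M and mitosis fell (camera adjusted p = 6.15e-18, and adjusted p = 0.129 with an estimated correlation). So did 38 of 41 genes of G1/S and DNA replication (adjusted p = 1.36e-17, and adjusted p = 0.0150 with an estimated correlation). In each of these lists 40 fell adjusted over the list alone. ANLN fell by 1.14, HMMR by a log2 change of -1.02 and RRM2 by -1.36. GAL, the neuropeptide galanin, fell by 2.90 (SE 0.13, adjusted p = 0.000301), GDF15, a stress-induced cytokine gene, fell by 2.63 (SE 0.076), and PSG8 was at least 2.04-fold lower (fitted log2 change -1.47 with the mean of its probes). Under normexp GAL was at -1.59 and PSG8 at -0.40. PIP rose by 4.94 (SE 0.48, adjusted p = 0.00206). TMEM71, BCAT1, CA8, ZNF655, JAKMIP1 and DDR2 were at least 30.1-fold, 9.83-fold, 7.73-fold, 7.63-fold, 7.51-fold and 6.95-fold higher. IMPG2, TDRD5, LRRTM1, YY1P2 and GALNT13 were at least 4.78-fold, 3.42-fold, 3.19-fold, 3.18-fold and 2.40-fold lower. Without siEGFP 96 h replicate 2 the bounds of JAKMIP1 and DDR2 were 4.34-fold and 3.48-fold. Without siEGFP 48 h replicate 2 that of LRRTM1 was 1.81-fold, and without replicate 1 that of TDRD5 was 1.64-fold and GALNT13 had none. The probes of TMEM71, BCAT1, ZNF655 and DDR2 were well above background on the siEGFP 96 h arrays only. Those of IMPG2, LRRTM1, YY1P2 and GALNT13 were so on the siEGFP 48 h arrays only. With both arrays also brighter than 64 units, as for TMEM71, BCAT1, ZNF655 and IMPG2, the pattern held for 8 probes per pair of arrays within groups. Between groups at the same time it held for 6.5 per pair. These means pool the times: the siEGFP 96 h arrays shared 9 such probes and the siEGFP 48 h arrays 2. The calls for DDR2 and JAKMIP1 ended without siEGFP 48 h replicate 1 (adjusted p = 0.0567 and 0.0594) or 2 (0.0575 and 0.0568). The calls for CA8 and GALNT13 ended without siEGFP 96 h replicate 1 (0.144 and 0.109) or 2 (0.125 and 0.105) and without siSALL3 48 h replicate 1 (0.0836 and 0.0621) or 2 (0.0844 and 0.0628). That of CA8 also ended without siEGFP 48 h replicate 1 or 2, and that of GALNT13 without siSALL3 96 h replicate 1 or 2. For CA8 the siEGFP arrays agreed within groups (-6.184 and -6.135 at 48 h, -1.131 and -1.567 at 96 h). The siSALL3 96 h arrays, whose spread enters the shared estimate, read -1.295 and -5.965. TDRD5 lost its call without siEGFP 96 h replicate 1 (adjusted p = 0.0742) or 2 (0.0703). Another TDRD5 probe, which did not meet the detection rule on all arrays together, took its place without siEGFP 48 h replicate 1 (-0.091), siSALL3 48 h replicate 2 or siSALL3 96 h replicate 1 (0.16 each). The tested TDRD5 probe itself was at -2.77 without siEGFP 48 h replicate 1, and leaving out siSALL3 arrays cannot change its value.

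With time in siEGFP cells 5945 genes passed limma's test, 2471 higher and 3474 lower. With no filter on dim probes 9687 were higher and 3004 lower. The count was 2851 and 2871 without siEGFP 48 h replicates 1 and 2, and 3892 and 3886 without siEGFP 96 h replicates 1 and 2.

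Camera called 10 lists with time in siEGFP cells, 6 without siEGFP 96 h replicate 1, and apart from G1/S and DNA replication none held with an estimated correlation. DNA repair genes fell in 20 of 27 cases and rose in 1 (adjusted p = 7.21e-08, and adjusted p = 0.129 with an estimated correlation). Basal mammary markers fell in 9 of 15 cases and rose in 0 (adjusted p = 0.000645, and adjusted p = 0.129 with an estimated correlation), with CAV1 at -1.71. Matrix remodelling genes fell in 10 of 20 cases and rose in 0 (adjusted p = 0.00349, and adjusted p = 0.129 with an estimated correlation). TGF-beta targets fell in 7 of 14 cases and rose in 0 (adjusted p = 0.0306, and adjusted p = 0.197 with an estimated correlation). Genes of amino acid stress and the unfolded protein response fell in 13 of 34 cases and rose in 3 (adjusted p = 0.0365, and adjusted p = 0.399 with an estimated correlation). Luminal mammary markers rose in 6 of 12 cases and fell in 0 (adjusted p = 0.00300, and adjusted p = 0.129 with an estimated correlation). Interferon-stimulated genes rose in 12 of 33 cases and fell in 2 (adjusted p = 0.00778, and adjusted p = 0.129 with an estimated correlation). Of the 33, 7 were not well above background on either array of at least 1 of the 2 groups. The rises include IFI44L (0.88), which was not well above background on any siEGFP array and was at 0.053 under quantile normalization. Lysosome and autophagy genes rose in 9 of 25 cases and fell in 2 (adjusted p = 0.0249, and adjusted p = 0.201 with an estimated correlation), with TFEB at 0.58 (0.22 with the mean of its probes, which ended its call with an adjusted p of 0.0640). Adjusted over the list alone, counts that rose and fell were 1 and 23 for DNA repair, 0 and 11 for matrix, 0 and 8 for TGF-beta, 3 and 14 for the unfolded protein response, 12 and 4 for interferon-stimulated and 12 and 3 for lysosome genes, and otherwise those given.

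Calls of lists with time that ended when an array was left out were these. The unfolded protein response lost its call without siEGFP 48 h replicate 1 (adjusted p = 0.0928) or 2 (0.0512) or siEGFP 96 h replicate 1 (0.0647). TGF-beta targets lost it without siEGFP 48 h replicate 2 (0.103), siEGFP 96 h replicate 1 (0.0701) or siSALL3 96 h replicate 1 (0.0529) or 2 (0.104). Lysosome genes lost it without siEGFP 96 h replicate 1 (0.0610) or 2 (0.123), and interferon-stimulated genes without siEGFP 96 h replicate 1 (0.0518). The ribosomal protein list passed without siEGFP 48 h replicate 1 (0.0389). The other 22 tested lists were not called with all arrays. Among those, median, mean and test differed in sign for p53 targets (median 0.0038, mean -0.024, test up), NF-kB genes (0.0027, -0.13, up; median 0.17 with dim groups set to the floor of the bounds), ERK feedback (-0.064, -0.060, up; median 0.019 at the floor), fatty acid synthesis (-0.027, 0.020, up) and NRF2 targets (0.012, -0.11, down).

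The siSALL3 effect at 96 h and the change with time in siEGFP cells were mostly of opposite sign, with 3781 genes called in opposite directions and 781 in the same. The siEGFP 96 h arrays enter both with opposite signs, which alone gave a simulated r of -0.503 across genes beside the observed -0.444. The covariance was -0.235 against -0.0225 simulated, a difference of -0.212. Part of the overlap may still come from the shared arrays, which are too few to split. The simulated groups had no change with time, so they allow only for shared noise. A change with time that was merely weaker in siSALL3 cells would also give opposite signs. Among genes called with time in siEGFP cells, the slope of the siSALL3 change with time on the siEGFP change was 0.245. The covariance therefore does not show that siSALL3 reversed the change with time.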

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

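The test of bright probes in this part was chosen only after the result was seen. The siSALL3 effect differed between 48 h and 96 h for 4465 genes by limma's test of the difference, 2378 with the larger value at 96 h and 2087 with the smaller, and the count was 2266 and 2309 without siEGFP 48 h replicates 1 and 2 and 2975 and 2750 without siSALL3 48 h replicates 1 and 2. Lists whose effect differed between the times by camera are given with the median difference (96 h minus 48 h). Positive were interferon-stimulated genes (1.52), basal mammary markers (0.76), matrix remodelling (0.72), cholesterol synthesis (0.71), mesenchymal genes (0.62), DNA repair (0.46), G1/S and DNA replication (0.46), amino acid stress and the unfolded protein response (0.29), and hypoxia and glycolysis (0.23). Negative were luminal mammary markers (-0.78), NRF2 targets (-0.69), NF-kB and inflammatory cytokines (-0.43), squamous differentiation (-0.39) and cytosolic ribosomal proteins (-0.26). With dim groups set to the floor of the bounds, the medians were 1.34 for interferon-stimulated, 0.71 for basal, 0.69 for matrix, 0.49 for mesenchymal, -0.41 for NF-kB and -0.42 for squamous genes, and the other 8 were unchanged. With an estimated correlation the calls held for interferon-stimulated genes (adjusted p = 0.0186), G1/S and DNA replication (adjusted p = 0.0213) and cholesterol synthesis (adjusted p = 0.0392), and for none of the other 11.

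The named genes with the largest differences between times were CMYA5 (4.61), IMPG2 (4.28), IFI44 (4.09), STARD4 (3.97) and ABCD2 (3.94) on the positive side, and TMEM71 (-6.67), ZNF655 (-4.62), BCAT1 (-4.60) and KRT72 (-4.52) on the negative side; only 4 named genes were eligible there because 1 gene was left out. These are fitted differences, since none of these genes was well above background in more than 1 group. Apart from KRT72, each was brighter than 64 units on both arrays of that group.

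A technical explanation for such genes is signal that switches on at random on single arrays, since 938 probes were bright on 1 array and not well above background on the other 7. Arrays of the same group shared 8 probes per pair that were bright on exactly those 2 arrays, and arrays of different groups at the same time 6.5, a ratio of 1.23 (exact binomial p = 0.356). Random signal may therefore account for many such genes. The siSALL3 96 h arrays shared 21, more than the 8 to 16 of the 96 h pairs of different groups, so a response to the siRNA stays open for CMYA5, IFI44, STARD4 and ABCD2. IFI44 belongs to the interferon-stimulated list, of which 27 of 33 genes rose and 1 fell at 96 h.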

How the results depend on the processing

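SALL3 at 48 h ranged from -0.21 to -0.061 and at 96 h from -0.47 to -0.40 when arrays were left out in turn, and each stayed on its side of the threshold under every setting run. Counts under the same omissions ranged from 3641 to 6689 at 48 h, 10479 to 11830 at 96 h, 8357 to 10506 for siSALL3 at 96 h against siEGFP at 48 h, 10739 to 12197 averaged over times, 2851 to 6388 with time, 2266 to 4754 for the difference between times, 3286 to 5674 at both times and 924 to 1498 for the study's rule; lists ranged from 3 to 7 at 48 h, 11 to 13 at 96 h and 6 to 10 with time. Fewer samples may account for lower counts, but this was not tested. The 96 h count was lower than with all arrays also where an array of a 48 h group was left out. Adding a 2-fold minimum left 905 genes at 48 h, 3647 at 96 h, 2899 against siEGFP at 48 h, 2075 averaged, 770 with time, 1255 for the difference between times and 776 at both times. With no filter on dim probes the counts were 4052 at 48 h, 18263 at 96 h (5830 up, 12433 down), 12691 with time (9687 up, 3004 down), 9992 for the difference (2055 up, 7937 down), 14556 averaged (5754 up, 8802 down), 3559 at both times and 1621 for the study's rule (642 up, 979 down). Dim probes then enter, and signal over background limits what they can show. The scaled level of background itself differed between groups. IMPG2, not well above background on any 96 h array, read -5.466 and -5.372 on siEGFP 96 h arrays. On siSALL3 96 h arrays it read -5.983 and -6.062. The 75th percentile signal used for scaling was 236 and 198 on the siEGFP 96 h arrays, against 288 and 297 on the siSALL3 96 h arrays. Normexp, which adds an offset that shrinks the folds of dim probes, gave 7039 for the difference between times and 258 for the study's rule. Of 376 called values of named genes, 135 moved over 1.5 times under it, all 135 toward 0. Bounds were not recomputed under it, and some fitted changes under it, such as those of ZEB1 and PLAU at 96 h, lay below the bounds given. The study's rule gave 2867 genes at over 1.5-fold and 459 with probes well above background on all 8 arrays. With the estimated correlation 0, 2 and 1 lists were called at 48 h, 96 h and with time, and with the mean of a gene's probes 8 lists at 48 h; the cause was not tested.

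Called values of genes and lists that reversed were KRT14 with time (0.38 with the mean of its probes), ZEB1 with time (0.12 under normexp), the ribosomal protein list at 96 h (0.086 under quantile normalization) and the mesenchymal list at 96 h (-0.013 with no filter). The cause was not tested. At the floor of the bounds, medians of lists without a call changed sign for NF-kB at 96 h (0.029 to -0.086). With time they did so for ERK feedback, the EGFR family (-0.0049 to 0.11) and mesenchymal genes (-0.088 to 0.085). TDRD5 with time (0.16 with no filter, and from -4.90 to 0.16 when arrays were left out in turn) reversed because another of its probes then stood for the gene, and the main probe stayed at -3.83 with no filter. For the named genes' other values, each value was counted again for every array left out and every other setting. When arrays were left out in turn, 265 of these comparisons lost a call and 39 gained a call, beside 3430 with no such change. Under other settings 108 comparisons lost a call and 64 gained a call, beside 4833 with no such change. The replicate numbers did not pair the samples: correlations of same-numbered deviations lay between -0.0767 and 0.0568. With the replicate number as a block the counts were 5760 at 48 h, 11614 at 96 h, 4904 with time and 3440 for the difference between times.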

Other observations

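The tests in this part were chosen only after the results were seen, except the count of splits of the arrays, whose limit to splits that keep the groups whole was also chosen afterwards, and the gene families here were chosen after their values were seen. Replication-dependent histone genes of the H1 to H4 clusters fell at 96 h in 57 of 61 cases and rose in 0, with a median of -1.04, although genes of G1/S and DNA replication rose at that time. At 48 h 21 fell and 1 rose (median -0.24), and with time in siEGFP cells 16 rose and 7 fell. H2AC19 fell by 2.08 at 96 h, and the copies are near-identical, so probes may not tell them apart. HLA class II genes fell at 96 h in 11 of 13 cases and rose in 0 (median -0.81), HLA-DRA with a log2 change of -2.04, while interferon-stimulated genes rose, and they had risen with time in siEGFP cells in 10 of 13 cases. Under normexp 12 fell and 1 rose at 96 h, and the 48 h median was 0.0074 in place of -0.20 (-0.054 and, at 96 h, -0.80 with dim groups set to the floor of the bounds). All 7 tested aldo-keto reductases of the AKR1B and AKR1C families fell at both times, with medians of -1.16 and -3.27. All 4 tested pregnancy-specific glycoprotein genes rose at both times, with medians of 1.37 and 3.40, and these too are near-identical copies. They were well above background on 3 to 6 arrays. Their medians were 1.17 and 1.28 with dim groups set to the floor of the bounds, and 0.37 and 0.68 under normexp. Each of these families kept the direction of its 96 h median under normexp, quantile normalization and median centring, of which the last only shifts each array as a whole. The authors' value table holds the same signal and adds no test.

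With time in siSALL3 cells, a contrast that shares no array with that in siEGFP cells, 5895 genes passed limma's test, 2752 higher and 3143 lower. Across genes the changes with time had a Pearson r of 0.279 between the siRNAs, and genes are not independent replicates. Of the 5945 genes called with time in siEGFP cells, 31.2% (1857) moved the same way past the threshold in siSALL3 cells and 748 the opposite way. Of 40 genes of G2/M and mitosis 36 fell in siSALL3 cells too (camera adjusted p = 8.61e-18, and adjusted p = 0.0553 with an estimated correlation). Of 41 genes of G1/S and DNA replication 16 fell and 1 rose, with a median closer to 0 than in siEGFP cells (-0.23; adjusted p = 0.000127, and adjusted p = 0.0553 with an estimated correlation). Of 33 interferon-stimulated genes 31 rose (adjusted p = 6.12e-24, and adjusted p = 0.00887 with an estimated correlation), and of 22 NRF2 targets 21 fell (adjusted p = 6.51e-13, and adjusted p = 0.0553 with an estimated correlation). Of 24 cholesterol synthesis genes 21 rose and 2 fell (adjusted p = 9.88e-10, and adjusted p = 0.0326 with an estimated correlation). Camera's other calls there were lost with an estimated correlation: YAP and TEAD targets, 7 of 13 higher (adjusted p = 0.000484, and adjusted p = 0.205 with an estimated correlation), mesenchymal genes, 6 of 16 higher and 1 lower (adjusted p = 0.00563, and adjusted p = 0.142 with an estimated correlation), and apoptosis regulators, 9 of 27 higher and 2 lower (adjusted p = 0.0339, and adjusted p = 0.229 with an estimated correlation). So were those of matrix remodelling, 6 of 20 higher and 2 lower (adjusted p = 0.0496, and adjusted p = 0.229 with an estimated correlation), and ribosomal proteins, 10 of 39 lower (adjusted p = 3.50e-05, and adjusted p = 0.573 with an estimated correlation).

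SALL3 fell little although 6615 genes changed at 48 h and 12102 at 96 h. Array scaling or background correction as the cause is argued against, since the lowest SALL3 change at 48 h was -0.16, under normexp and quantile normalization. Median centring, which only shifts each array as a whole, gave -0.13. The authors' value table holds the same signal and adds no test. An exchange of single arrays between groups is argued against by the correlations across genes, whose lowest within a group (0.992) lay above the highest between groups (0.984), a difference of 0.00764, and an exchange of whole groups by the SALL3 means, of which no pair of groups differed by more than 0.43 (95% interval 0.25 to 0.61), short of a 2-fold loss. Whether the probe also reads other transcripts cannot be told apart from a small loss, because SALL3 had 1 probe. Recovery of the RNA between 48 h and 96 h is argued against, since the change at 96 h lay below that at 48 h (difference -0.30, 95% interval -0.55 to -0.044, limma adjusted p = 0.0916 over all genes), while recovery before 48 h and action of the siRNA on other transcripts stay open and untested.

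HMMR fell by 3.06 at 48 h, and the other 39 tested genes of G2/M and mitosis lay between -0.49 and 0.45. Fewer dividing cells would move these genes together, but HMMR lay 2.57 below the lowest of them (a gap of -2.57). The gap was -2.33 under normexp and -2.58 under quantile normalization. Median centring shifts each array as a whole and cannot change the gap, and the authors' value table holds the same signal, so these alternatives add no test. Direct action of the siRNA on unintended transcripts may account for it, since the fall was complete at 48 h for HMMR (difference between times 0.20, adjusted p = 0.186), whereas 274 genes over 2-fold lower at 48 h had a median difference of -0.58. This test separates little, because 99 of the 274 genes (36.1%) also had a difference above -0.3, and the siRNA sequence is not given in the sources used here. An effect of SALL3 on HMMR stays open as well.

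For the siSALL3 effect averaged over times, a fit without time gave 7590 genes for the real split of the arrays into 4 and 4. The highest of the other splits, the split by time, gave 389 genes. All 35 splits were to be counted, but the samples of a group may not be separate cultures, and each split that parts a group gave 0 genes. Only 3 splits keep the groups whole, of which 1, the real one, gave as many genes, and these are too few for a share under 0.05.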
